A study of Mus musculus with 5 samples.

How the data were processed

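Cells of advanced pancreatic tumours from KPPC and KPPCN mice were profiled by droplet single-cell RNA sequencing with the 10x Genomics 3′ V3 chemistry, which counts unique molecular identifiers (UMIs) near the 3′ end of transcripts. Per the labels' protocols, mice were 7 to 8 weeks old, dead cells and CD45-positive cells were depleted, about 6000 cells were loaded per library, and single-end reads of 98 bp were sequenced. The labels give 3 mice of each genotype. Libraries of 3 KPPC and 2 KPPCN tumours were analysed here. The KPPCN libraries carry numbers 1 and 2, and the KPPC libraries carry the codes C3, D3 and H2, which do not match the numbers of the KPPC samples. The labels describe samples with the same replicate number as processed in parallel, but without numbers for KPPC this batch could not be entered in any test. The p-values of single genes and of shares rest on the spread between these 5 libraries. Those of camera with a preset correlation compare a list with the other genes and do not measure that spread.

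The submitters' processing notes name Cell Ranger 2.1.0, R 3.5.1, Seurat 3.0.2 and the genome build GRCm38, without saying what each was used for. Filters on cells and genes were not given in the sources used here. The deposited values are on a natural log scale: in every cell the exponential minus 1 summed to 10000, so that a value is the natural log of 1 plus the UMIs per 10000. UMIs were recovered by dividing by the smallest step in each cell, and 100% of the values came out whole within 0.01 UMI. Depth therefore stayed known, although the tables held normalised values. Genes numbered 12579 in the KPPC table and 31053 in the KPPCN table. All tests used the 12579 shared genes, which held 99.3% of the KPPCN UMIs. Every gene of the KPPC table was found in at least 37 cells, whereas the KPPCN table also listed genes found in 0 cells. Genes nearly absent from KPPC could therefore not be tested, and their gains in KPPCN would be missed. No KPPC cell had under 503 genes and the highest mitochondrial share in either table was 5.00%, whereas KPPCN cells went down to 43 genes.

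Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept. This left out 801 of 17771 barcodes (733 in KPPCN 1 and 68 in KPPCN 2). A doublet caller that scores cells against simulated doublets marked 86 cells (0.507%), which were left out, so that 16884 cells were used. It detected 2.04 to 22.7% of its own simulated doublets, so many doublets can remain. Cells were clustered on 2000 variable genes, 30 principal components and 20 nearest neighbours with the Leiden method at resolution 1, which gave 33 clusters, and at resolutions 0.5 and 2 as alternatives (23 and 45 clusters). Libraries were not integrated. Marker genes of 15 cell classes were fixed before the data were examined. A cluster was named when its best class scored 1.5 or more, led the next class by 0.5, and had at least 3 markers raised 2-fold, and when doublets made up no more than 50% of it. Its 2 leading genes also had to hold no marker of another class. A cluster whose cells held under 0.333 of the median UMIs of their own libraries, with no marker of its class among its top 10 genes, stayed unnamed as well. Clusters 12 and 24 reached the scores for the erythroid class, but cells of cluster 12 held 0.203 of their libraries' median UMIs with none of these markers among the top 10 genes, and Igkc, a B/plasma marker, led cluster 24. By this rule 23 clusters were named and 10 stayed unnamed. The rule for naming was set after the clusters had been seen. Cluster 17 and cluster 27 held more markers of another class than of their own among their top 10 genes and are given by number.

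UMIs were summed per library and cell population wherever a library held at least 20 cells. Because the tables held log values, the planned count models were not run on the recovered UMIs and were replaced by limma on log2(CPM + 5), with trimmed-mean scaling computed for this work, precision weights from counting and between-library variance, a moderated test with a trend, and Benjamini-Hochberg adjustment at 0.05. The weights were added because simulated data gave false calls without them, and the counts of genes called were 0 with and without them. Genes entered with at least 10 UMIs at the median total and 15 UMIs over all libraries. Fold changes on this scale understate the change of genes near or below 5 CPM. Lists of genes (23, fixed before the data were examined) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list moves one way and does not compare it with other genes. A list needed 5 measured genes. With an estimated correlation no list passed in any population, and fry called none. Besides the 3 planned populations with enough cells, clusters 8, 10, 12 and 18 were tested together, a comparison added after the clusters had been seen. Shares of cells were compared by two-sided exact permutation tests, for which 3 against 2 libraries give 10 splits and a smallest p of 0.1. Chance alone puts the groups apart for 20% of genes in that design, and 32.5, 21.1 and 27.6% of genes lay apart in the epithelial-like cells, in clusters 8, 10, 12 and 18 and in the fibroblast-like cells. Shares of cells with a UMI were compared after thinning every cell to 1000 UMIs.

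Genes named in the text followed a rule fixed before the data were examined: up to 4 members of each list described, those with the largest log2 difference among members at 20 CPM or more in a genotype, plus Nsdhl. A gene that the rule names is not reported here. The part of the rule that ranks genes past the threshold named none. Genes that define clusters or bear on a hypothesis were chosen after the values had been seen.

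The tests of single genes, of lists and of differences between cell populations were first run on simulated counts. In these, 200 well-covered genes were changed by known factors. Simulated genes varied independently, so these runs do not check the preset correlation of camera. The tests of shares, p53 targets, doublets and epithelial RNA were not simulated. The simulated spread came from the KPPC libraries alone. Its dispersion was 0.00675 in the epithelial-like design, 0.0212 in clusters 8, 10, 12 and 18 and 0.00961 in the fibroblast-like cells. The real sums had squared coefficients of variation of 0.0145, 0.0336 and 0.0173, so the numbers of changed genes called can be too high for the real data. In the epithelial-like design 39 of 67, 65 of 67 and 66 of 66 genes changed 2-, 4- and 8-fold were called, with 38 of 11893 unchanged genes called. In clusters 8, 10, 12 and 18 these were 60 of 67, 67 of 67 and 66 of 66 with 7 of 11062, in the fibroblast-like cells 67 of 67, 67 of 67 and 66 of 66 with 15 of 11654, and in the endothelial-like cells 0 of 67, 47 of 67 and 57 of 66 with 36 of 10511. The test of a difference between epithelial-like and fibroblast-like cells, run without precision weights or a trend, called 316 of 392 changed and 58 of 11067 unchanged genes. The test of chromosome profiles gave spreads of at least 0.182 in 10 simulated draws with a 1.5-fold gain of 2 chromosomes and at most 0.0998 without.

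Alternatives were another scaling, no filter on low UMIs, a stricter cell filter (1000 genes, 10% mitochondrial UMIs), doublets kept, each library left out, other cluster resolutions and leukocytes left out of the denominator. Added after seeing the data were a pseudocount of 1 CPM, sums thinned to the smallest total, no precision weights, and clusters included in or left out of a population. Gene positions came from the GENCODE vM21 annotation of GRCm38. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1.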

Results

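Single-cell RNA libraries of advanced pancreatic tumours were compared between 2 mouse genotypes. KPPC mice develop pancreatic carcinoma and lack both copies of Trp53 in the Pdx1-Cre lineage, which gives rise to the pancreas. KPPCN mice lack Nsdhl in addition. NSDHL is a sterol dehydrogenase of the late steps of cholesterol synthesis, and the study asked how blocking this pathway bears on TGFβ signalling and on the basal differentiation of the carcinoma. Tumours came from mice 7 to 8 weeks old, and dead cells and CD45-positive cells were depleted before loading. The KPPC libraries, named C3, D3 and H2, held 3774, 3273 and 2500 cells after filtering, with 80434302, 75337763 and 50839984 UMIs. KPPCN 1 held 5325 cells with 26946391 UMIs, and KPPCN 2 held 2012 cells with 52899517 UMIs. Median depth per cell was 17355, 19018 and 17904.5 UMIs in KPPC and 21718.5 UMIs in KPPCN 2, against 2166 UMIs in KPPCN 1. Each library was taken as 1 tumour, and a KPPCN tumour beyond these was not analysed here.

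Nsdhl (ENSMUSG00000031349, chromosome X, 72918557 to 72958514 on the plus strand of GRCm38) was read in every library. Over all cells it stood at 15.2, 18.1 and 16.8 CPM (UMIs scaled to a total of 1e+06 per library) in KPPC C3, D3 and H2, at 13.6 CPM in KPPCN 1 (exact Poisson 95% interval 12.3 to 15.1) and at 11.6 CPM in KPPCN 2 (10.7 to 12.5). In the epithelial-like cells it stood at 30.5, 24.1 and 28.6 CPM in KPPC, at 38.3 CPM in KPPCN 1 (25.7 to 55.0, from 29 UMIs) and at 38.8 CPM in KPPCN 2 (23.7 to 59.9, from 20 UMIs). The log2 difference was 0.37 with an SE of 0.23 (limma, adjusted p = 0.818). In the fibroblast-like cells it was −0.47 with an SE of 0.18 (adjusted p = 0.575). A 3′ tag that lies outside the deleted part of a gene does not check the deletion. Which part of Nsdhl is deleted was not given in the sources used here, so these values were not read as a check of the labels. The intervals cover counting error only.

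Epithelial-like cells, named from markers such as Epcam and Krt19, made up 14.8, 28.0 and 25.8% of cells in the KPPC libraries and 1.20 and 1.39% in KPPCN 1 and 2 (mean 22.9 ± 7.10%, SD, n = 3, against 1.30 ± 0.13%, n = 2). Endothelial-like cells made up 6.38 ± 1.84% against 0.926 ± 1.15%, mesothelial-like cells 9.75 ± 2.80% against 1.66 ± 0.022%, pericyte-like cells 1.27 ± 0.68% against 0.0376 ± 0.053%, and cluster 17 (led by Ins2, Ins1 and Iapp) 3.49 ± 0.55% against 0.915 ± 0.38%. In these 5 populations both KPPCN libraries lay below all 3 KPPC libraries. The two-sided exact permutation test gave p = 0.1 for each of them (Benjamini-Hochberg p = 0.3), and 0.1 is the smallest p that 10 splits of 3 against 2 libraries allow. The shares of a library depend on each other, and clusters 8, 10, 12 and 18 took up 72.5% of KPPCN 2, which lowers every other share there. The 5 lower shares are therefore not 5 separate results, and a denominator without these clusters was not tested. Fibroblast-like cells made up 27.06 ± 15.05% against 21.99 ± 12.33% (exact permutation p = 0.8), and that difference turned positive without leukocytes in the denominator (27.7 against 35.5%). It also turned positive, to 2.01 points without KPPC C3 and to 3.65 points without KPPCN 2.

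T/NK-like cells reached 24.6% and B/plasma-like cells 20.2% in KPPCN 1, whereas KPPCN 2 held 1 T/NK-like cell (0.0497%). All leukocyte classes together made up 46.6% of KPPCN 1, 0.845% of KPPCN 2 and 2.03 ± 0.54% of the KPPC libraries (exact permutation p = 0.4). Without KPPCN 1 the differences for T/NK-like and B/plasma-like cells turned negative (−0.55 and −0.14 points). CD45 depletion acts on exactly these classes, and the lower depth of KPPCN 1 acts on every class. With at least 1000 genes per cell the difference in B/plasma-like cells was 0.52 points in place of 9.93, and that in T/NK-like cells 5.23 in place of 11.7. Clustering at the lower resolution put the epithelial-like difference at −8.04 points in place of −21.6 and the mesothelial-like difference at −18.6 points in place of −8.09. There a cluster led by Ins2, with Epcam and Krt7 among its top 10 genes, stayed unnamed. It held 232, 449 and 323 KPPC cells and 38 and 24 KPPCN cells. A cluster led by Cdkn2a, with 311 cells of KPPCN 2, was named epithelial-like there. The epithelial-like differences at these resolutions therefore describe different cells.

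**Figure D1:**
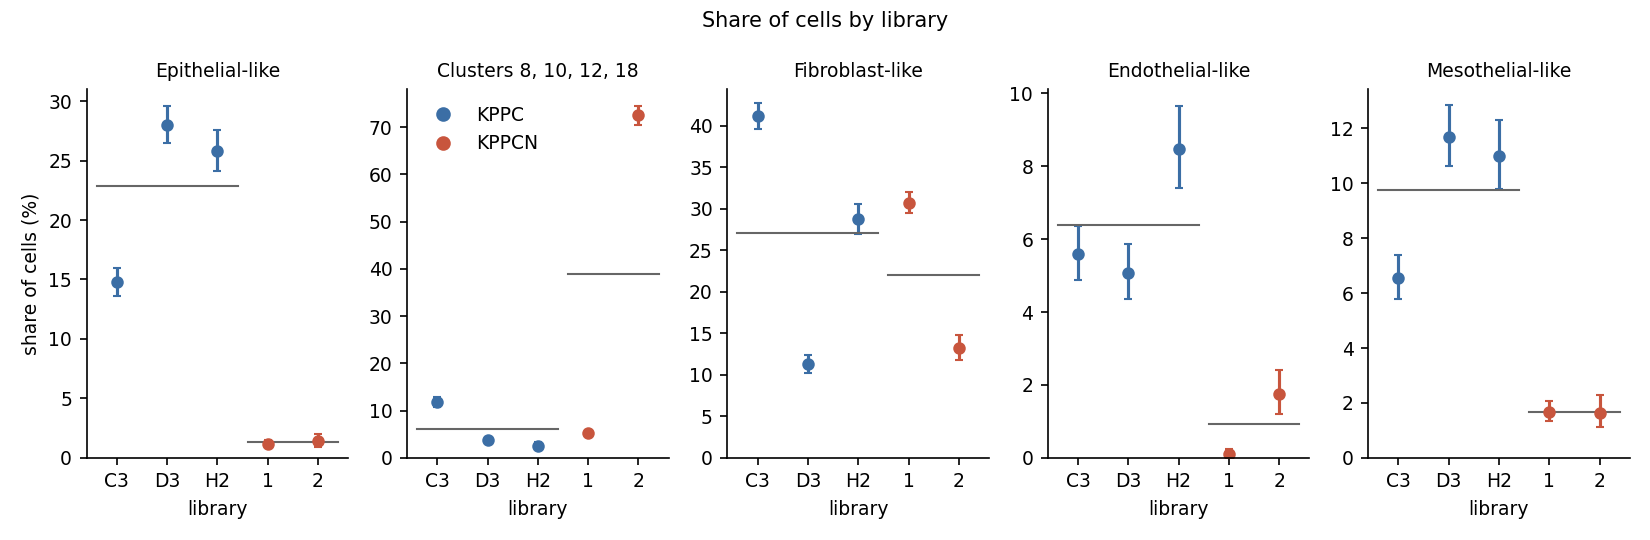
Share of all cells (%, vertical axis) of 5 populations in each library, KPPC in blue and KPPCN in red, with exact 95% binomial intervals (counting error only) and horizontal lines at the genotype means. The epithelial-like share lies between 14.8 and 28.0% in the KPPC libraries and at 1.20 and 1.39% in the KPPCN libraries, and clusters 8, 10, 12 and 18 make up 72.5% of KPPCN 2 alone.

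Epcam, an adhesion gene of epithelial cells, gave the same order without any clustering. With every cell thinned to 1000 UMIs, 14.02, 24.4 and 22.1% of KPPC cells held an Epcam UMI, against 1.57% in each KPPCN library. The unthinned values were 35.2, 52.8 and 42.1% against 4.68 and 5.61%. The fibroblast-like cells of the same libraries, which should lack Epcam, gave 2.19, 2.20 and 1.26% in KPPC and 0.395 and 0.376% in KPPCN after thinning, at median depths of 17926, 13962.5 and 17360.5 UMIs and 4276 and 19832 UMIs before it. Thinning left out 43, 62 and 16 KPPC cells and 491 and 32 KPPCN cells.

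Clusters 8, 10, 12 and 18 held RNA of a simple epithelial keratin and of mesenchymal genes and received no class name. Cdkn2a, a cell cycle inhibitor, and Hmga2, a chromatin protein of fetal tissue and tumours, were among the 10 leading genes of each of the 4 clusters, so they define the clusters and are not compared between genotypes. Flt1 and Grem1 led cluster 8, and Hmga2 and Ankrd1 cluster 18. Krt18, a simple epithelial keratin, stood at 544 to 3202 CPM in these clusters, and Vim, the mesenchymal intermediate filament, at 3396 to 5554 CPM, above its 2393 to 2933 CPM in the fibroblast-like cells. Epcam stood at 1.45 to 72.9 CPM, against 706 to 1837 CPM in the epithelial-like cells. Dcn, a fibroblast proteoglycan, stood at 26.3 to 244 CPM, against 3935 to 8417 CPM in the fibroblast-like cells. The 4 clusters made up 11.8, 3.79 and 2.56% of the KPPC libraries, 5.18% of KPPCN 1 and 72.5% of KPPCN 2 (6.05 ± 5.01%, n = 3, against 38.8 ± 47.6%, n = 2, exact permutation p = 0.2), and without KPPCN 2 the difference turned to −0.86 points. Of the epithelial-like cells plus the 4 clusters, epithelial-like cells made up 55.6, 88.1 and 91.0% in KPPC and 18.8 and 1.88% in KPPCN. The exact permutation p was 0.1, its smallest possible value. That difference was −67.9 points, and −59.4 points without KPPCN 2. In KPPCN 1 it went with a low epithelial-like share, since 5.18% for the clusters lay within the KPPC range. Clusters 8 and 18 held 57.0% of the cells of KPPCN 2 and 0.121% of the KPPC cells on average, and clusters 10 and 12 held 5.93 ± 5.05% of KPPC and 10.3 ± 7.37% of KPPCN cells. The rule for a name was set after the clusters had been seen. It also left unnamed clusters 4, 7 and 22 (19.04 ± 12.6% of KPPC and 4.38 ± 3.99% of KPPCN cells), cluster 14 (8.88% of KPPCN 1 and no cell of the other libraries) and clusters 24 and 31 (0.0930 and 1.37%).

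**Figure D2:**
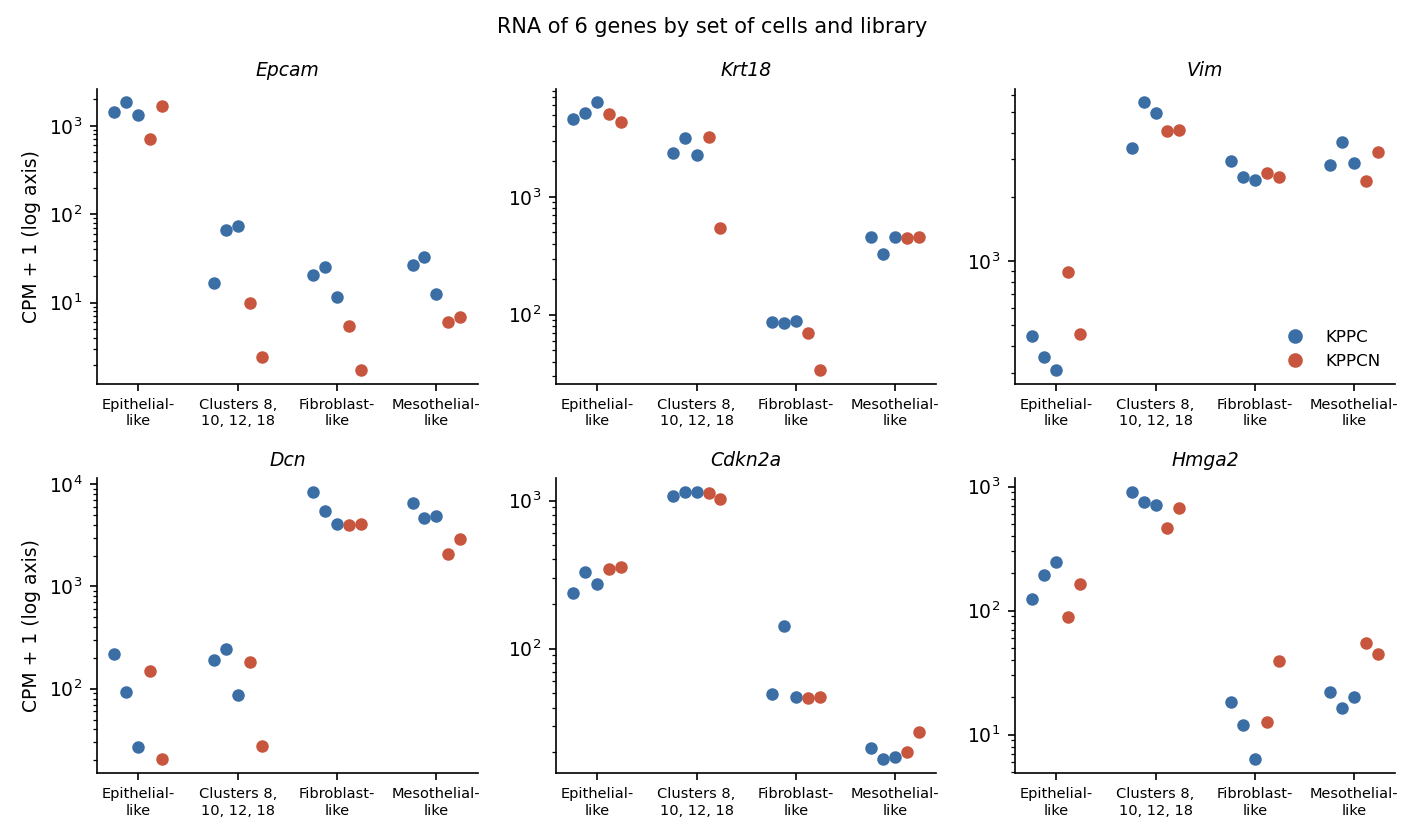
RNA of 6 marker genes (CPM + 1, log axis) in the summed cells of 4 populations, 1 point per library, KPPC in blue and KPPCN in red. Clusters 8, 10, 12 and 18 hold Krt18 at 544 to 3202 CPM with Epcam at 1.45 to 72.9 CPM and Dcn at 26.3 to 244 CPM.

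In the epithelial-like cells, the genes of cholesterol synthesis and uptake rose together in KPPCN. All 25 measured members were higher in KPPCN on average, by 0.64 on the log2 scale over the list (camera, adjusted p = 1.57e-12; adjusted p = 0.847 with an estimated correlation), and for 17 of them both KPPCN libraries lay above all KPPC libraries. In the comparisons of genes between genotypes CPM were taken on totals scaled by trimmed means, whereas the CPM of Nsdhl and of Krt18, Vim, Epcam and Dcn by population rest on unscaled totals. Pmvk, the phosphomevalonate kinase, stood at 54.2, 38.9 and 52.8 CPM in KPPC C3, D3 and H2 and at 88.2 and 131 CPM in KPPCN 1 and 2 (log2 difference 1.04 ± 0.27, SE). Fdps, the farnesyl diphosphate synthase, stood at 177, 148 and 217 against 301 and 403 CPM (0.91 ± 0.26). Cyp51, the lanosterol demethylase, stood at 83.8, 62.2 and 94.7 against 131 and 185 CPM (0.89 ± 0.29). No single gene passed limma's test in this population (0 of 12152 at an adjusted p of 0.05, with a lowest adjusted p of 0.765 and 781 genes at an unadjusted p under 0.05), and adjusted over the list alone 0 of the 25 passed. The comparison rests on 557, 917 and 645 KPPC cells against 64 and 28 KPPCN cells. Cluster 5, led by Tff2 and Reg1, held 319, 364 and 304 of the KPPC cells, 49 of those of KPPCN 1 and 13 of those of KPPCN 2, and cluster 9, led by Epcam and Krt7, held 156, 372 and 227 of the KPPC cells, 6 of those of KPPCN 1 and 11 of those of KPPCN 2. With clusters 10 and 12 counted as epithelial-like, the list difference was 0.22 and no longer passed (adjusted p = 0.111). These 2 clusters added 442, 120 and 60 KPPC cells and 271 and 312 KPPCN cells, so they weigh more in the KPPCN sums. In KPPCN 1 and 2 the list mean was 5.33 and 5.06 in clusters 8, 10, 12 and 18, against 6.03 and 6.35 in the epithelial-like cells.

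**Figure D3:**
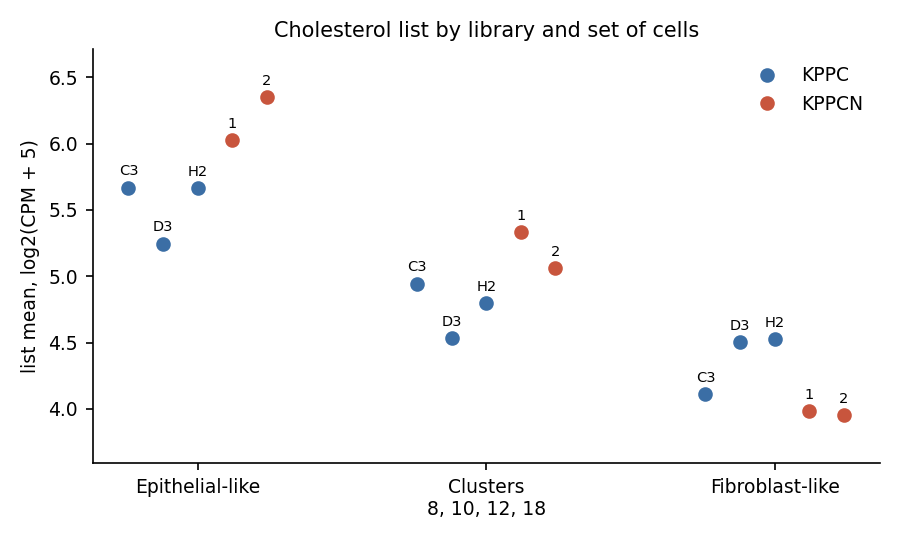
Mean of the 25 cholesterol genes (log2 of CPM + 5, vertical axis) in each library and set of cells, KPPC in blue and KPPCN in red. In epithelial-like cells the KPPCN libraries stand at 6.03 and 6.35 and the KPPC libraries between 5.25 and 5.67, and in fibroblast-like cells at 3.98 and 3.95 against 4.11 to 4.53.

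A further 4 lists passed camera in the epithelial-like cells, each with an adjusted p of 0.847 once the correlation was estimated. Fatty acid synthesis rose (10 of 13 genes higher, mean 0.29, adjusted p = 0.0208), with Fasn, the fatty acid synthase, at 59.5, 54.4 and 61.3 against 111 and 88.9 CPM (0.75 ± 0.18, SE) and the elongase Elovl6 at 0.44 ± 0.30. Hypoxia and glycolysis rose (12 of 20 higher, mean 0.20, adjusted p = 0.0317), with the prolyl hydroxylases Egln3 at 0.95 ± 0.42 and P4ha1 at 0.95 ± 0.35. Proliferation genes fell (18 of 20 lower, mean −0.46, adjusted p = 0.0111), with the cyclin Ccnb2 at 12 and 2 UMIs (16.0 and 3.63 CPM) in KPPCN against 34.4, 32.6 and 29.9 CPM in KPPC, and the replication factor Mcm6 at −0.75 ± 0.25. Antigen-presentation genes rose (7 of 9 higher, mean 0.70, adjusted p = 0.0213), with Cd74 at 13.3, 27.6 and 7.96 against 114 and 19.97 CPM. KPPCN 1 was 46.6% leukocytes, and its 64 epithelial-like cells held 12 UMIs of the leukocyte gene Ptprc and 20 of the B cell gene Cd79a, against 0 of both in those of KPPCN 2. Each of these 4 calls changed with a single library left out. Without KPPCN 1, hypoxia and antigen presentation turned to −0.071 and −0.31, fatty acid synthesis stood at 0.20 (adjusted p = 0.14) and proliferation at −1.18. With thinned sums fatty acid synthesis stood at 0.25 (adjusted p = 0.0854) and hypoxia at 0.14 (adjusted p = 0.152), and without precision weights hypoxia stood at 0.15 (adjusted p = 0.155) and antigen presentation at 0.55 (adjusted p = 0.104). With clusters 10 and 12 included, fatty acid synthesis stood at 0.096 (adjusted p = 0.487), antigen presentation at 0.64 (adjusted p = 0.068) and hypoxia at 0.63. Proliferation turned to 0.33 and passed upwards there (adjusted p = 0.0139). Without KPPCN 2, proliferation turned to 0.050, fatty acid synthesis stood at 0.36 (adjusted p = 0.103), hypoxia at 0.40 and antigen presentation at 1.39. The number of lists past the threshold, 5 of 23, was 10 without KPPC C3 or without KPPC H2, and 3 without KPPCN 2.

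The lists nearest to the study's question did not pass in the epithelial-like cells. For TGFβ ligands and receptors the adjusted p was 0.975, with a list median of 0.11, a mean of −0.081 and a test direction upwards, so that these differ in sign. Thbs1, which activates latent TGFβ, stood at −0.72 ± 0.33 (log2, SE) and the activin subunit gene Inhba at −0.61 ± 0.40, which turned to 0.13 without KPPCN 1 and was −1.10 without KPPCN 2. Of 18 measured SMAD target genes 13 were lower (mean −0.22, adjusted p = 0.146), with Ctgf at 102.8, 80.1 and 78.6 against 36.1 and 61.7 CPM and Tgif1 at −0.71 ± 0.38. Mesenchymal genes gave an adjusted p of 0.146, and their members went both ways. S100a4, a calcium-binding protein of mesenchymal cells, stood at 23.9, 27.6 and 28.0 against 88.2 and 47.2 CPM (1.22 ± 0.25) and was the 1 gene past the threshold when adjusted over the list alone, whereas the osteopontin gene Spp1 stood at −1.27 ± 0.34. Of 20 epithelial genes 14 were lower (adjusted p = 0.212), with Cldn4, a tight junction gene, at −1.29 ± 0.46. Classical subtype genes gave an adjusted p of 0.399 with 2 of 24 lower when adjusted over the list alone, and the gastric gene Gkn3 stood at 785, 1293 and 1336 against 287 and 454 CPM (−1.66 ± 0.38). For the basal subtype, 15 of 25 genes were measured and 10 of them were lower (mean −0.37, adjusted p = 0.146). A gene missing from the KPPC table could not count as higher. Krt16, a stress keratin of squamous epithelium, stood at 25.3, 77.3 and 24.6 CPM in KPPC and at 1 and 4 UMIs in KPPCN, and the lysosomal protease gene Ctsl stood at −0.90 ± 0.30.

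In clusters 8, 10, 12 and 18, a comparison added after the clusters had been seen, cholesterol genes again rose in KPPCN. Of 25 genes 23 were higher, by a mean of 0.41 (camera, adjusted p = 8.95e-06; adjusted p = 0.464 with an estimated correlation), and 4 passed when adjusted over the list alone. Fdps stood at 90.9, 58.2 and 76.0 CPM in KPPC and at 188 and 160 CPM in KPPCN (log2 difference 1.17 ± 0.25, SE), and Mvd, the mevalonate diphosphate decarboxylase, at 0.83 ± 0.21. Without KPPCN 1 the list difference was 0.29 and did not pass (adjusted p = 0.0747). Fatty acid synthesis rose too (mean 0.25, adjusted p = 0.0364, and adjusted p = 0.427 with an estimated correlation), a call lost without KPPC H2 (0.21), KPPCN 1 (0.29) or KPPCN 2 (0.18), with clusters 8 and 18 left out (0.22, adjusted p = 0.0712), with thinned sums (0.24, adjusted p = 0.0631) and with a pseudocount of 1 CPM (0.30, adjusted p = 0.0707). No single gene passed limma's test (0 of 11367, with 836 at an unadjusted p under 0.05), but without KPPCN 1, which leaves KPPCN 2 as the lone KPPCN library, 266 genes were called higher and 380 lower. The sums held 445, 124 and 64 KPPC cells and 276 and 1459 KPPCN cells. The cells of KPPCN 1 came mostly from cluster 10 (247) and those of KPPCN 2 from clusters 8 (792), 18 (355) and 12 (308), while cluster 10 held 221, 108 and 48 of the KPPC cells.

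The same clusters showed more TGFβ ligand and matrix RNA in KPPCN. TGFβ ligands and receptors rose (11 of 14 higher, mean 0.34, adjusted p = 0.0142, and adjusted p = 0.427 with an estimated correlation), with Inhba, itself among the 10 leading genes of cluster 8, at 271, 331 and 324 against 508 and 532 CPM (0.75 ± 0.20, SE) and Tgfb2 at 7.32, 15.7 and 20.2 against 15.5 and 82.2 CPM. SMAD targets did not pass (13 of 18 higher, adjusted p = 0.131). Among them Pmepa1, a feedback inhibitor of TGFβ signalling, stood at 587, 779 and 573 against 1260 and 1109 CPM (0.87 ± 0.22), Tagln, an actin-binding gene that is also on the myofibroblast list, at 1.35 ± 0.38, and Cyr61 at 0.96 ± 0.24. Extracellular matrix genes rose (20 of 25, mean 0.53, adjusted p = 1.68e-04), with the collagen genes Col5a1 at 49.6, 49.4 and 45.8 against 120 and 202 CPM and Col5a2 at 1.56 ± 0.48. Mesenchymal genes rose (15 of 19, mean 0.44, adjusted p = 0.00454), with Mmp2 at 1.42 ± 0.58 and Cdh11 at 8.42, 18.1 and 11.4 against 7.47 and 200 CPM, while Spp1 stood at −1.53 ± 0.43. Myofibroblast genes rose (12 of 14, mean 0.66, adjusted p = 2.46e-04), with Acta2 at 1.26 ± 0.41, and this call held with each library left out in turn. With an estimated correlation the adjusted p was 0.427 for matrix, mesenchymal and myofibroblast genes alike. Without KPPCN 1 the means were 0.31 for TGFβ ligands (adjusted p = 0.248) and 0.31 for matrix genes (adjusted p = 0.22), and without KPPCN 2 the mesenchymal mean was 0.21 (adjusted p = 0.338). With clusters 8 and 18 left out, TGFβ ligands stood at 0.22 (adjusted p = 0.0911) and mesenchymal genes at 0.28 (adjusted p = 0.108). The difference of the differences between the whole set of clusters and fibroblast-like cells was tested after the results had been seen. It passed camera for TGFβ ligands (0.55, adjusted p = 0.00179), SMAD targets (0.45, adjusted p = 0.0019), matrix (0.70), mesenchymal (0.50) and myofibroblast genes (1.27). With an estimated correlation these adjusted p were 0.364 to 0.539. SMAD targets moved by 0.21 here and by −0.25 in fibroblast-like cells.

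Epithelial genes fell in these clusters (16 of 16 lower, mean −1.13, adjusted p = 1.26e-09, and adjusted p = 0.464 with an estimated correlation), with Epcam at 17.1, 63.5 and 68.6 against 9.002 and 1.42 CPM on scaled totals. Classical subtype genes fell as well (19 of 20, mean −1.19, adjusted p = 6.99e-11, and adjusted p = 0.427 with an estimated correlation), with the mucosal gene Dmbt1 at 170, 108 and 55.2 against 12.8 and 9.99 CPM (−2.78 ± 0.37, SE) and the trefoil gene Tff2 at −2.43 ± 0.27. Dmbt1 stood at like levels in the fibroblast-like cells of the same libraries, at 182, 119 and 89.7 against 22.7 and 12.4 CPM. The falls were not shown to differ from those in the fibroblast-like cells (difference of the differences −0.041 for epithelial and −0.030 for classical genes, camera adjusted p = 0.657 and 0.531). Without KPPCN 2 the means of these lists were −0.26 (adjusted p = 0.0583) and −0.24 (adjusted p = 0.0374). Basal subtype genes fell (9 of 12, mean −0.46, adjusted p = 0.0247, and adjusted p = 0.513 with an estimated correlation), with Ctsl at −1.05 ± 0.26, a call lost without KPPC C3 (−0.34), KPPC D3 (−0.31) or KPPCN 2 (−0.029), with clusters 8 and 18 left out (−0.14), with thinned sums (−0.30) and without precision weights (−0.28). Hypoxia genes rose (19 of 20, mean 0.59, adjusted p = 3.50e-05, and adjusted p = 0.590 with an estimated correlation), with the vasodilator gene Adm at 1.44 ± 0.51 and Egln3 at 39.7, 29.4 and 39.7 against 40.8 and 248 CPM. That mean was 0.064 without KPPCN 2 (adjusted p = 0.666) and 1.07 without KPPCN 1. Interferon genes rose (15 of 18, mean 0.40, adjusted p = 0.0495, and adjusted p = 0.761 with an estimated correlation), with Ifit3 at 1.52 ± 0.61, and the call, though not the sign, was lost without KPPC C3 (0.16), KPPC H2 (0.27), KPPCN 1 (0.36) or KPPCN 2 (0.40), with clusters 8 and 18 left out (0.18) and without a filter on low UMIs (0.36). With clusters 8 and 18 left out the epithelial mean was −0.73. The interferon mean was 0.73 without KPPC D3.

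In the fibroblast-like cells the cholesterol list moved the other way. Of its 25 genes 24 were lower in KPPCN, by a mean of −0.39 (camera, adjusted p = 8.15e-08; adjusted p = 0.535 with an estimated correlation), and 0 passed when adjusted over the list alone. Cyp51 stood at 26.7, 55.7 and 64.3 CPM in KPPC and at 17.7 CPM in both KPPCN libraries (log2 difference −1.14 ± 0.33, SE), and Hmgcs1, which opens the mevalonate pathway, at −0.77 ± 0.25. LXR targets, the sterol-induced genes of cholesterol export, fell (6 of 8, mean −0.39, adjusted p = 0.0271, and adjusted p = 0.535 with an estimated correlation), with Apoe at −1.53 ± 0.61 and Pltp at −0.50 ± 0.16, and without KPPCN 2 their mean was −0.21 (adjusted p = 0.412) and with cluster 19 left out −0.35 (adjusted p = 0.0517). No single gene passed limma's test (0 of 11933, with 1031 at an unadjusted p under 0.05), and without KPPC C3 50 genes did, 40 of them higher. The sums held 1555, 368 and 718 KPPC cells and 1635 and 267 KPPCN cells. Cluster 1, led by Sned1 and Dpt, was 97.7% KPPCN 1, and cluster 0, led by Dpt and Dcn, was 64.9% KPPC C3.

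Proliferation genes rose in the fibroblast-like cells of KPPCN (20 of 20, mean 0.56, adjusted p = 3.06e-09, and adjusted p = 0.535 with an estimated correlation), with Mki67 at 29.2, 17.7 and 20.2 against 86.4 and 25.8 CPM and Cenpf at 1.04 ± 0.39 (log2, SE). Cluster 19, with Mki67 and Cenpf among its 10 leading genes, held 53, 5 and 5 of the KPPC and 121 and 6 of the KPPCN cells. With it left out the mean was 0.21 (adjusted p = 0.0166). It was 0.30 without KPPCN 1 and 0.96 with cluster 1 left out. Interferon genes rose (18 of 20, mean 0.45, adjusted p = 3.37e-04, and adjusted p = 0.581 with an estimated correlation), with Ifi27l2a at 554, 383 and 273 against 918 and 1123 CPM and Irf7 at 1.17 ± 0.43. Their mean was 0.058 without KPPCN 2 (adjusted p = 0.879), 0.91 without KPPCN 1 and 0.27 without KPPC H2. Hypoxia genes rose (19 of 20, mean 0.29, adjusted p = 0.00321, and adjusted p = 0.635 with an estimated correlation), with the phosphofructokinase Pfkp at 0.56 ± 0.15. That mean turned to −0.083 without KPPCN 2, stood at 0.75 without KPPCN 1 and did not pass without KPPC C3 (0.20). Myofibroblast genes fell (13 of 15, mean −0.52, adjusted p = 6.00e-04, and adjusted p = 0.535 with an estimated correlation), with Igfbp3 at 164, 880 and 262 against 84.2 and 155 CPM and Myl9 at −1.16 ± 0.49, and with cluster 1 left out the mean was −0.16 (adjusted p = 0.345). Genes of endothelium and angiogenesis fell (11 of 15, mean −0.20, adjusted p = 0.00745, and adjusted p = 0.498 with an estimated correlation), with the chemokine gene Cxcl12 at −1.15 ± 0.49 and the VEGF receptor gene Flt1 at 0.69 ± 0.59. Their mean was −0.060 without KPPCN 1 and −0.31 without KPPCN 2. SMAD targets did not pass (adjusted p = 0.124), with Cdkn2b at −1.32 ± 0.35 and Tgfbi at −1.13 ± 0.28.

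Epithelial and classical subtype genes, which mark another cell type, fell in the fibroblast-like cells (16 of 16 and 18 of 19 lower, means −0.92 and −1.05, adjusted p = 2.00e-16 and 7.95e-17, and an adjusted p of 0.498 for both with an estimated correlation). Krt7 stood at 49.3, 55.4 and 38.1 against 16.2 and 2.63 CPM, and Gkn3 at 16.6, 52.3 and 27.9 against 1.56 and 1.13 CPM. By 11 epithelial markers, epithelial RNA made up 2.07, 2.49 and 1.477% of the fibroblast-like sums of KPPC C3, D3 and H2 and 0.837 and 0.385% of those of KPPCN 1 and 2.

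Endothelial-like cells were compared between 211, 166 and 212 KPPC cells and 35 cells of KPPCN 2, since KPPCN 1 held 6. With a lone KPPCN library the values describe that library, and no list test is given. Interferon genes were higher in KPPCN 2 than the KPPC mean (19 of 20, mean log2 difference 1.76), with the antiviral effector Ifit3 at 24.3, 9.33 and 11.7 CPM in KPPC and at 181 CPM in KPPCN 2. TGFβ ligands and receptors were higher in 13 of 14 (mean 0.66), with Ltbp1, a latent TGFβ binding protein, at 1.18 and Tgfb3 at 1.17. Epithelial and classical genes were lower (14 of 14 and 14 of 16, means −1.90 and −1.56), with Krt19 at 94.9, 89.1 and 46.3 CPM against 2 UMIs in KPPCN 2. The limma test of single genes assumes here that the lone library varies as the KPPC libraries do. In simulation this design called 0 of 67 genes changed 2-fold, so nothing is read from its count of genes. Cluster 27 (led by Lyz2 and Cd74) held 18, 13 and 3 KPPC cells and was not tested.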

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

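Of the tests in this part, those of doublets, of leukocytes in the denominator, of shallow cells and of genotype were chosen after the result had been seen, and those of p53 targets, chromosome profiles and epithelial RNA before. That of thinned sums was added after the data had been seen, but before its own result. The test of differences between cell populations was also chosen after the result had been seen.

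The difference between KPPCN and KPPC was not the same by camera in epithelial-like and fibroblast-like cells for 6 lists, tested as the difference of the differences. Unlike the other tests, this one used neither precision weights nor a trend. It was 1.08 on the log2 scale for cholesterol genes (camera, adjusted p = 3.05e-19, and adjusted p = 0.624 with an estimated correlation), 0.36 for fatty acid synthesis (adjusted p = 8.68e-04), 0.81 for epithelial genes, 0.67 for classical subtype genes, −1.14 for proliferation (adjusted p = 3.79e-12) and 0.59 for myofibroblast genes. The epithelial and classical lists moved by −0.19 and −0.18 in epithelial-like cells and by −0.92 and −1.05 in fibroblast-like cells, whose epithelial RNA was lower in KPPCN (0.837 and 0.385% against 1.477 to 2.49%). With an estimated correlation none of the 6 passed (lowest adjusted p = 0.624), and 0 of 11574 single genes passed limma's test of the difference, with 1315 at an unadjusted p under 0.05. Between clusters 8, 10, 12 and 18 and fibroblast-like cells, lists also passed camera. Among them were cholesterol (0.85, adjusted p = 8.76e-15), proliferation (−0.60, adjusted p = 7.59e-07) and the TGFβ and matrix lists given above. None passed there with an estimated correlation (lowest adjusted p = 0.364), and 0 of 11115 single genes passed limma's test.

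The cholesterol list was higher in epithelial-like and lower in fibroblast-like cells of KPPCN, so that epithelial-like minus fibroblast-like levels were 1.56, 0.74 and 1.14 in KPPC C3, D3 and H2 and 2.05 and 2.401 in KPPCN 1 and 2. Epithelial RNA in the fibroblast-like sums was argued against as the main source, because it accounted for 6.72% of the loss from 524 to 335 CPM over the list. Shallow KPPCN sums were argued against as well. With all sums thinned to the smallest total the epithelial-like difference was 0.745 over 24 measured genes, in place of 0.641 over 25. Genotype stays open, since the exact permutation p of 0.1 is the smallest that 3 against 2 libraries allow, and so does the difference in clusters between KPPCN 1 and the other libraries.

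The lower epithelial-like share in KPPCN was weighed next. Leukocytes in the denominator were argued against, because without them the difference was still −21.5 points. Shallow cells that lose their class were argued against, because at 1000 UMIs per cell no KPPCN library passed 1.57% of cells with an Epcam UMI, against at least 14.02% in KPPC. Whether genotype, tumour stage or dissociation set the share cannot be told apart with an exact permutation p of 0.1 at its floor.

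Clusters 8, 10, 12 and 18 may hold carcinoma cells that lost epithelial features. Doublets of epithelial-like and fibroblast-like cells were argued against, since Epcam stood at 0.0868 to 5.46% of its epithelial-like level where Krt18 stood at 12.6 to 63.0%, a ratio of at most 0.154. Between-library differences by chromosome were larger than in fibroblast-like cells in 10 of 10 library pairs (median SD 0.192 against 0.0529, with 0.0847 in epithelial-like and 0.0319 in mesothelial-like cells), as clones with gains and losses would give, while differences in cell state between tumours stay open as another source. The p53 target list was below its fibroblast-like level in all 5 libraries (highest median −0.0917), but so it was in mesothelial-like cells, and not in all epithelial-like sums, so this list does not tell loss of Trp53 from a difference between cell types. Trp53 itself stood at 10.6 to 13.4 CPM here and at 3.96 to 13.6 CPM in epithelial-like cells. Both lay below its 30.1 to 46.6 CPM in fibroblast-like and 55.1 to 70.7 CPM in mesothelial-like cells. Loss of Trp53 in the lineage could give such lower levels, but a difference between cell types could too. The Trp53 levels do not tell these apart, so the lineage stays open.

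Genes listed only in the KPPCN table entered no comparison, and 5924 of 18474 had more than 3 UMIs there. Ptprc, the gene of CD45, had 4010 UMIs in KPPCN 1, in 2084 of 5325 cells. The developmental transcription factor genes Pax6 and Irx1 and the synaptic gene Cbln1 had 2176, 2975 and 4831 UMIs in KPPCN 2, of which 94.8, 95.3 and 94.6% lay in clusters 8 and 18, which held 75.6% of all UMIs of that library.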

How the results depend on the processing

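The alternatives named with a pseudocount, thinned sums, precision weights or clusters left out or included were chosen after seeing the data. No paired analysis was possible because the KPPC libraries carry no replicate numbers, so the planned replicate block was not run. The planned Wald count test and the macrophage comparison were not run either. Leaving out KPPCN 2 gave no value in endothelial-like cells, and leaving out KPPCN 1 changed nothing there. Of the results that answer a comparison, 258 values under alternatives were tallied as unchanged. For differences this meant the same direction and side of the threshold. For counts of genes or lists it meant a change within 1.5 times, and for Nsdhl levels a value within the interval. Of the others, 21 counts moved by over 1.5 times or away from 0, 8 differences lost the threshold and 8 changed sign. For single genes and other lists, 1337 kept direction and side of the threshold. A further 91 lost and 17 gained the threshold and 15 changed sign. The first tally includes differences of shares, whose exact permutation p cannot fall below 0.1, so none could cross the threshold of 0.05. For them only a change of sign was open, and their size was not weighed. The epithelial-like difference was −8.04 points at the lower resolution in place of −21.6, where the rule gave this name to other cells. Some differences were 0 there because no cluster received the class, so they show no direction.

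Genes called numbered 0 in each population. With each library left out they ranged from 0 to 2 in epithelial-like cells (2 without KPPC H2), from 0 to 646 in clusters 8, 10, 12 and 18 (646 without KPPCN 1) and from 0 to 50 in fibroblast-like cells (50 without KPPC C3), and with clusters 10 and 12 included there were 2 in epithelial-like cells. Lists past the threshold in epithelial-like cells ranged from 3 to 10 around 5 with each library left out, and were 3 without precision weights and 11 with clusters 10 and 12 included. In clusters 8, 10, 12 and 18 they ranged from 7 to 10 around 11, and were 8 with clusters 8 and 18 left out. With an estimated correlation they were 0 in all 4 populations, under each alternative run too. By fry they were 0 as well, but in fibroblast-like cells fry called 1 without KPPC C3 (lowest adjusted p = 0.0333) and 2 with cluster 1 left out (0.0486). With an estimated correlation the cholesterol differences of 0.64, 0.41 and −0.39 in epithelial-like cells, clusters 8, 10, 12 and 18 and fibroblast-like cells lost the threshold, though not their size, which shows that the preset correlation carries these calls. The epithelial-like difference was 0.22 with clusters 10 and 12 included, which make up more of the KPPCN than of the KPPC sums. The difference in clusters 8, 10, 12 and 18 ranged from 0.29 to 0.56 with each library left out. The causes were not tested.

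Signs changed as follows, and the cause was not tested. The ranges with each library left out run between the value without KPPCN 1 and that without KPPCN 2. In this order, they were −0.071 and 0.40 for hypoxia, −1.18 and 0.050 for proliferation, −0.31 and 1.39 for antigen presentation, 0.13 and −1.10 for Inhba and −2.13 and 0.11 for Cenpf in epithelial-like cells. With clusters 10 and 12 included, proliferation was 0.33 and passed upwards (adjusted p = 0.0139), Nsdhl −0.11, Inhba 0.90 and Cenpf 0.040. In clusters 8, 10, 12 and 18 the pairs were −0.021 and 0.56 for Nsdhl, 3.65 and −0.39 for Cdh11 and −3.90 and 0.43 for Krt7. In fibroblast-like cells they were 0.75 and −0.083 for hypoxia, 1.12 and −0.055 for P4ha1 and 2.01 and −0.36 for Flt1. For differences of shares in points they were −0.14 and 20.001 for B/plasma-like cells, −0.55 and 24.02 for T/NK-like cells, −0.23 and 1.21 for cluster 27, 66.5 and −0.86 for clusters 8, 10, 12 and 18, and −13.8 and 3.65 for fibroblast-like cells. The fibroblast-like difference was also 1.51 with the stricter cell filter, 7.78 without leukocytes and 2.01 without KPPC C3.

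In the epithelial-like sums of 64 and 28 KPPCN cells 1 UMI stood for 1.32 and 1.94 CPM on unscaled totals, which limits what can be read of genes near that level.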

Other observations

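The values in this part were chosen after they had been seen.

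Krt5 and Trp63, a keratin and a transcription factor gene of basal epithelium, were read in the KPPCN libraries only. Krt5 had 0 UMIs in both, and Trp63 had 3 UMIs in KPPCN 1 and 0 in KPPCN 2. Both were not analysed here in KPPC.

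Chromosome-wide medians in clusters 8, 10, 12 and 18 against fibroblast-like cells stood furthest from 0 at −0.78 for chromosome 10 and 0.50 for chromosome 3 in KPPCN 2, 0.55 for chromosome 15 in KPPC C3, and −0.61 and −0.57 for chromosome 7 in KPPC H2 and KPPCN 2 (log2).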
